A study of Danio rerio with 2 samples.

How the data were processed

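Single-cell RNA sequencing (10x droplets) was done on sorted cells of whole zebrafish embryos at 36 hours post fertilization, raised at 28.5 °C. Per the labels, the embryos carried a 2A-Venus insertion at etv2, a 2A-Gal4 insertion at jam2b and a UAS reporter for mCherry. There were 2 libraries, 1 of Venus-sorted cells (etv2_Venus) and 1 of mCherry-sorted cells (jam2b_mCherry). Cells positive for both reporters were split by hand and added in equal parts to both sorts, per the labels, so double-positive cells are present in each library. The labels' protocols name a cold protease dissociation.

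The deposited values are whole-number UMI counts per gene and barcode, in matrices the authors made with Cell Ranger 3.0.2, per the submitters' processing notes. Partek is also named there, without a version. The genome build and annotation are not given in the sources used here. Both matrices held 32523 features, of which 32520 had Ensembl identifiers and 3 were added rows (GAL4, eGFP and ets1a). Of the Ensembl identifiers, 29201 were found in the gene name table at hand, and symbols were taken as the files pair them with identifiers. A total of 3956 features had a symbol that occurs more than once, and features were kept apart by identifier. No row is named for Venus or mCherry. Whether reads of Venus were counted on the eGFP row is not stated in the sources used here.

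Barcodes were kept with at least 500 genes and under 10% mitochondrial UMIs. In the etv2_Venus library 554 of 8588 barcodes were below 500 genes and 51 were over the mitochondrial limit. In the jam2b_mCherry library these were 585 and 77 of 8282. Doublets were scored per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.06. Its own threshold marked 0.0116% of the etv2_Venus cells, which is below the 0.5% set as the least for a working threshold, so the 6% with the highest scores were removed there (515 cells). In the jam2b_mCherry library its own threshold marked 1.41% (117 cells). The cells used were 7537 in the etv2_Venus library, with 39149254 UMIs, and 7582 in the jam2b_mCherry library, with 41967734 UMIs. A total of 24 barcode sequences occurred in both libraries.

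Both libraries were clustered together without integration, from counts scaled to 10000 per cell and log-transformed, with 2000 variable genes, 40 principal components, 20 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, seed 0). Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used. The 33 clusters were named "-like" from fixed marker lists. A marker counted for a cluster when it was at least 2-fold above the other cells and at least 25% of its highest cluster. A name needed 3 markers and no lead of another class among the 10 leading genes. Clusters that failed these conditions stayed unnamed and are given by number. No deposited cell annotation was used here.

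There was 1 library per group, so no p-value, standard error or count of tested genes is given, and no difference has a replicate check. UMIs were summed per library and cell class and scaled to the total of the sum (CPM). Sums have exact Poisson 95% intervals, shares have exact Clopper-Pearson 95% intervals, and ratios of sums have exact conditional binomial 95% intervals. All of them cover counting error only. The upper limit given with a share of 0 is 3 counts over the total number of cells. A gene was called higher when its CPM ratio was at least 2, its interval excluded 1 and both libraries together held at least 200 UMIs (all cells) or 100 UMIs (within a class). For cells with and without a jam2b UMI the minimum was 50 UMIs. For single clusters held by both libraries it was 20 UMIs, and for progenitor-like cells with and without a gh1 UMI no minimum was set. Where a sum was 0, folds were computed against 3 counts over the group and are given as "at least". Shares of cells with a UMI were also computed after thinning each cell to 2000 UMIs, leaving out shallower cells. Neural progenitor-like cells served as the background class for etv2, jam2b and kdrl. For jam2b this departs from the plan, which named erythroid-like cells, of which the jam2b_mCherry library held 0. Neural progenitor-like cells of that library passed the mCherry sort, so they are not known to lack jam2b.

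Named genes followed a fixed rule. The targeted genes and reporters came first, then the 12 genes with the largest log2 CPM ratio in each direction among those called, with a prior of 1 UMI, leaving out clone-named, mitochondrial and ribosomal protein genes. For the fixed gene lists, 2 to 4 members with the most UMIs were named. A list's median log2 ratio over members with at least 20 UMIs was placed among 10000 random lists of the same size, matched on mean expression in 25 bins, as a description of these libraries. The lists covered arterial, venous, lymphatic, vascular progenitor, mature endothelial, endocardial, mesothelial, hypoxia, VEGF receptor, Notch, BMP, Hedgehog, Wnt, retinoic acid, extracellular matrix, junction, epithelial-mesenchymal transition, proliferation, dissociation stress, apoptosis, glycolysis, oxidative phosphorylation, iron and lipid transport genes.

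The calling steps were tested on simulated data drawn from the real sums, with Poisson noise only and no variation between cells. Over all cells (12428 genes), 91% of genes changed 3-fold and 93% of those changed 6-fold were recovered, and 0 of 12244 unchanged genes were called. A shifted list of 12 genes fell at percentile 100 and an unshifted one at 99.1. Within vascular endothelial-like cells (9398 genes), 62% and 81% were recovered, 128 of 9201 unchanged genes were called, and the lists fell at percentiles 100 and 86.5.

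The grouping, the comparisons, the markers, the gene lists, the size and naming rules and a set of other settings were fixed before the data were examined. Those settings changed the barcode and doublet filters, the resolution, the joint clustering, the variable genes, the scaling, the UMI minimum, the thinning and the number of UMIs required. Further settings were chosen after seeing the data: another doublet rule, a matched cluster mix, clusters of each library alone named against both, a class kept at 1000 genes per cell, wider vascular cell sets, blood-like cells left out, and all settings for the progenitor-like cells. The comparisons within progenitor-like cells and within cluster 0 were also added after seeing the data.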

Results

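Transcripts were counted in single cells sorted from zebrafish embryos at 36 hours post fertilization that carry reporters at etv2 (ENSDARG00000053868), which encodes an ETS transcription factor of early endothelial and blood cells, and at jam2b (ENSDARG00000079071), which encodes a junctional adhesion molecule. The etv2_Venus library held 8588 barcodes with 43391503 UMIs and a median of 4029 UMIs per barcode. The jam2b_mCherry library held 8282 barcodes with 43442989 UMIs and a median of 4882. After filtering, 7537 etv2_Venus cells (median 4189 UMIs and 1548 genes) and 7582 jam2b_mCherry cells (median 5091 UMIs and 1625 genes) were compared. Each group has 1 library, so no difference below has a replicate check, and all intervals (95%, exact) cover counting error only.

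The first question was which cell types each sort contained. Vascular endothelial-like cells made up 68.1% of the etv2_Venus library (5133 cells, 67.0 to 69.2%) and 1.07% of the jam2b_mCherry library (81 cells, 0.849 to 1.33%). With each library clustered on its own, the etv2_Venus share was 43.1%, and 67.0% when markers of those clusters were compared with cells of both libraries. Vascular progenitor-like cells, marked by etv2, tal1, lmo2, npas4l, fli1b and tmem88a, were 226 cells of the etv2_Venus library (2.63 to 3.41%) and 19 cells of the jam2b_mCherry library (0.151 to 0.391%), and these names shifted when the jam2b_mCherry library was clustered alone. On its own it held 1.33% vascular endothelial-like and 0% progenitor-like cells, and with markers compared against both libraries 0% and 1.33%, for the same cluster. The progenitor-like share of the etv2_Venus library was 5.92% with markers of its own clusters compared against both libraries. Endocardium-like cells made up 0.982% of the etv2_Venus library, and 0 were found in the jam2b_mCherry library, which allows a share of up to 0.0396% (3 counts over the total). Macrophage-like cells accounted for 5.19% and 0.317%, neutrophil-like cells for 2.32% and 0.0132%, and erythroid-like cells for 0.703% and 0% (at most 0.0396%), in the same order of libraries. The sort itself sets these shares.

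Mesodermal classes filled much of the jam2b_mCherry library. Lateral plate mesoderm and mesothelium-like cells (cluster 1, with hand2, jam2b, wt1a, aldh1a2, osr1 and bnc2) were 16.4% of it, against 0.0398% of the etv2_Venus library. Swim bladder and gut mesenchyme-like cells (cluster 10, with foxf1, barx1, nkx2.3, nkx3.3 and hlx1) were 7.66% against 0.172%, pectoral fin bud mesenchyme-like cells were 16.0% against 2.67% (cluster 2, with tbx18 and tbx5a, at 15.7% against 0.252%, and cluster 22, with and1 and and2, at 0.303% against 2.41%), and cardiomyocyte-like cells (cluster 27, with myl7, myh6, cmlc1, tnnt2a and nkx2.5) were 114 cells (1.24 to 1.80%) against 0 cells (at most 0.0398%). Cluster 5, led by pitx1, pcolcea, sema3e and hhip, held 11.1% of the jam2b_mCherry cells, and cluster 6, led by runx3, notum1b, sfrp5 and tbx5a, held 9.76%. Both stayed unnamed because genes of another class were among their leading genes. The class with the largest share of its markers was lateral plate mesoderm for cluster 5 and pharyngeal arch mesenchyme for cluster 6. Clusters 1, 5, 6, 10 and 27 together held 46.4% of the jam2b_mCherry library (3519 cells) and 0.279% of the etv2_Venus library (21 cells).

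Ectodermal and muscle classes were present in both sorts. Neural progenitor-like cells were 15.4% of the jam2b_mCherry library and 3.95% of the etv2_Venus library, and neuron-like cells were 3.69% and 0.849%. Epidermis-like cells were 4.91% and 1.11%, sclerotome and fibroblast-like cells 3.23% and 1.05%, and skeletal muscle-like cells 0.594% and 0.491%. Pigment-like cells were 0.765% and 0.305%, and otic and lateral line-like cells 0.765% and 0.0531%. Unnamed clusters held 27.4% of the jam2b_mCherry cells and 9.01% of the etv2_Venus cells. Among them, cluster 18, with etv2, eGFP, aqp8a.1 and hoxc13b among its leading genes, held 283 etv2_Venus cells and 0 jam2b_mCherry cells.

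**Figure D1:**
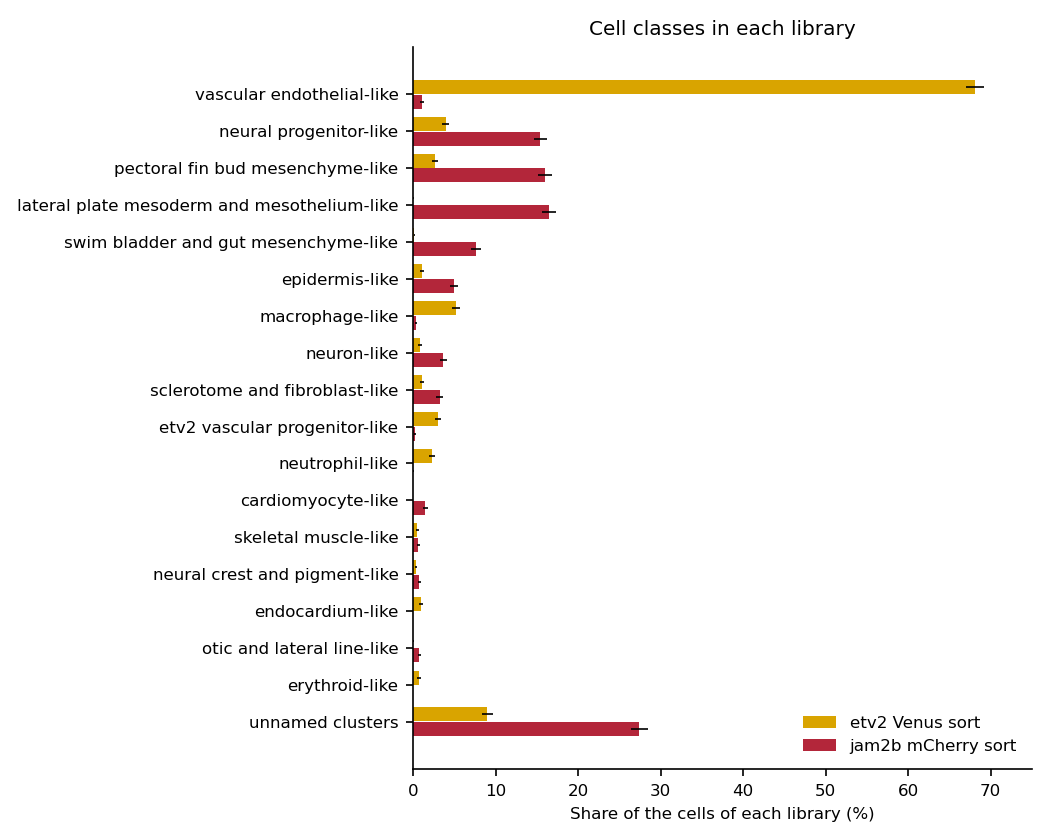
Share of the cells of each library (percent) in each named class and in the unnamed clusters, with exact binomial 95% intervals that cover counting error only. Vascular endothelial-like cells are 68.1% of the etv2_Venus library (43.1% with that library clustered on its own) and 1.07% of the jam2b_mCherry library.

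Vascular cells of the jam2b_mCherry library were spread differently over the vascular clusters. Over the vascular endothelial-like, progenitor-like, endocardium-like and cluster 18 cells together (5716 etv2_Venus and 100 jam2b_mCherry cells), cluster 0, led by lyve1b, meox2a, nrp2b, sele and tek, held 46.0% of the jam2b_mCherry cells (36.0 to 56.3%) and 24.1% of the etv2_Venus cells (23.0 to 25.2%). The progenitor-like cluster held 19.0% (11.8 to 28.1%) and 3.95% (3.46 to 4.49%). Other settings drew cluster 18 cells into this class in the etv2_Venus library alone (446 against 18 cells with 3000 variable genes and etv2 and jam2b left out of them, 501 against 9 without the 6% of highest doublet scores in both libraries). With cluster 18 counted in, a comparison chosen after seeing the data, the shares were 19.0% and 8.90% (8.18 to 9.67%). Cluster 3, led by apln, esm1, flt1 and dll4, held 6 cells of the jam2b_mCherry library (2.23 to 12.6%) and 18.1% of the etv2_Venus cells (17.1 to 19.1%). Cluster 11, led by slc16a1a, hbegfb and igfbp1a, held 2.00% (0.243 to 7.04%) and 10.1% (9.33 to 10.9%). For cluster 12, led by cxcl12a and stab2, the shares were 13.0% (7.11 to 21.2%) and 9.06% (8.33 to 9.84%), a difference not detectable at this depth.

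The targeted genes followed the sorts. Over all cells etv2 stood at 339 CPM in the etv2_Venus library and 7.93 CPM in the jam2b_mCherry library, and jam2b at 3.98 and 115 CPM. Progenitor-like cells had the highest etv2 level of the named classes, at 1387 CPM in the etv2_Venus library and 1053 CPM in the jam2b_mCherry library, against 448 and 222 CPM in vascular endothelial-like cells. In the jam2b_mCherry library jam2b reached 492 CPM in cardiomyocyte-like cells, 396 CPM in cluster 5, 254 CPM in cluster 1, 205 CPM in cluster 10 and 82.3 CPM in cluster 6, and 12.1 CPM in fin bud mesenchyme-like cells. The GAL4 row, part of the jam2b reporter, followed the same clusters, with 40.6 CPM in cluster 5, 27.2 CPM in cardiomyocyte-like cells and 25.4 CPM in cluster 1. The eGFP row stood at 865 CPM in progenitor-like and 201 CPM in vascular endothelial-like cells of the etv2_Venus library, and at 0 UMIs in neural progenitor-like cells, which allows up to 2.10 CPM in the etv2_Venus and 0.498 CPM in the jam2b_mCherry library.

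Within vascular cells jam2b was low. A jam2b UMI was found in 1.17% of vascular endothelial-like cells of the etv2_Venus library (median 3530 UMIs) and in 5 of 81 (6.17%, 2.03 to 13.8%) of the jam2b_mCherry library (median 4225 UMIs), against 0.671% and 2.99% of neural progenitor-like cells (medians 4157 and 4148 UMIs). In progenitor-like cells the shares were 4.87% (2.45 to 8.54%) and 15.8% (3.38 to 39.6%, 3 of 19 cells), at medians of 7330 and 9570 UMIs. Thinned to 2000 UMIs, vascular endothelial-like cells had a jam2b UMI in 0.688% and 3.17% of cells, and neural progenitor-like cells in 0.386% and 1.14%. By share of cells, the intervals of vascular endothelial-like and neural progenitor-like cells overlapped in each library. In the jam2b_mCherry library this overlap cannot show that jam2b in vascular cells is at background. Neural progenitor-like cells there passed the mCherry sort, and those of the etv2_Venus library stood at 1.40 CPM of jam2b (0.170 to 5.07). By summed UMIs, jam2b stood at 23.8 CPM (10.9 to 45.2, 9 UMIs) in vascular endothelial-like and 6.81 CPM (4.89 to 9.24) in neural progenitor-like cells of the jam2b_mCherry library. GAL4 had 0 UMIs in the 81 vascular endothelial-like cells of that library, which allows up to 7.94 CPM.

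The endothelial receptor gene kdrl (ENSDARG00000105215), looked at here after its values were seen, was also found outside the vascular clusters. In the jam2b_mCherry library it stood at 119 CPM in cluster 1 and 113 CPM in cluster 5, with a UMI in 40.5% and 32.1% of cells, against 394 CPM in vascular endothelial-like cells, 15.4 CPM in cluster 6, 14.1 CPM in cluster 10 and 0.248 CPM in fin bud mesenchyme-like cells. As background, 0.770% of neural progenitor-like cells of that library had a kdrl UMI (medians 5056, 4295 and 4148 UMIs for cluster 1, cluster 5 and neural cells). Thinned, 18.7% of the cells of clusters 1 and 5 had a kdrl UMI. In the same clusters etv2 stood at 2.28 and 1.62 CPM. The paralog kdr had 4 UMIs over both clusters.

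**Figure D2:**
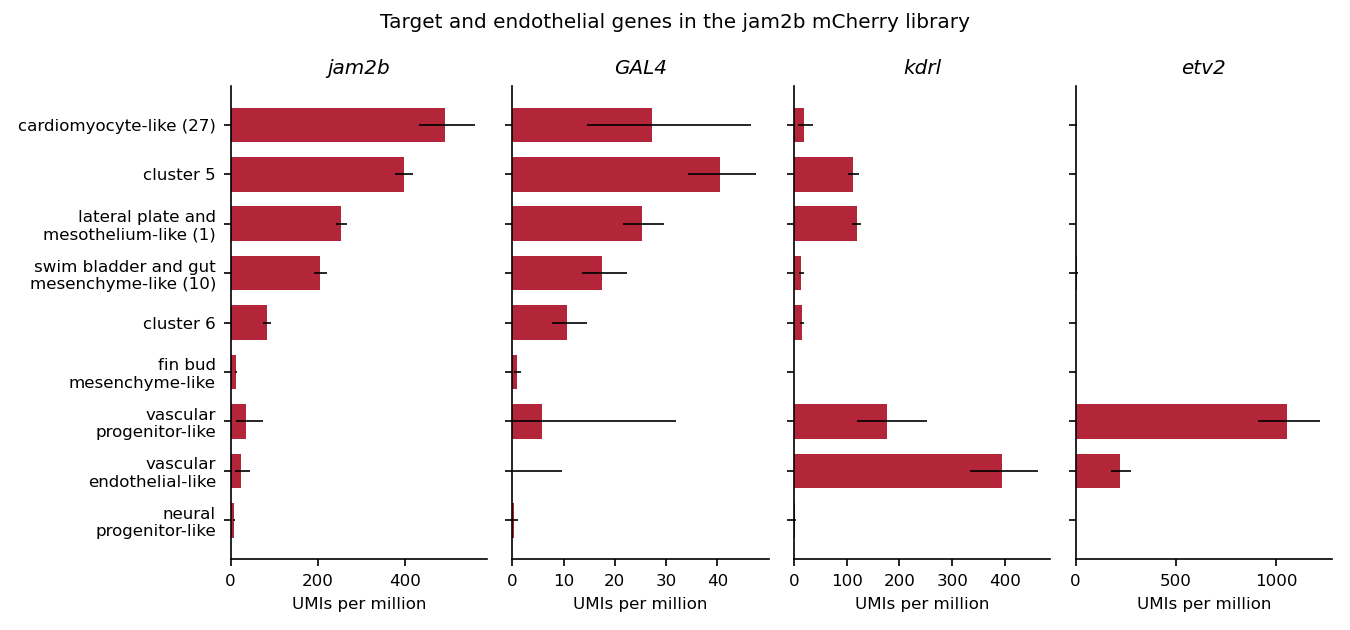
CPM of jam2b, GAL4, kdrl and etv2 in classes and clusters of the jam2b_mCherry library, with exact Poisson 95% intervals that cover counting error only and a separate scale for each gene. Levels of jam2b are highest in cardiomyocyte-like cells and clusters 5, 1 and 10, kdrl is present in clusters 1 and 5 at 119 and 113 CPM, and etv2 is highest in progenitor-like cells at 1053 CPM.

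Because double-positive cells were added to both sorts, cells with UMIs of both targeted genes were counted. In the etv2_Venus library 65 of 7537 cells (0.862%, 0.666 to 1.098%) had UMIs of both etv2 and jam2b, and in the jam2b_mCherry library 35 of 7582 cells (0.462%, 0.322 to 0.641%). If both genes were detected independently, 73.4 and 35.7 such cells would be counted. Of the 65 etv2_Venus cells, 43 were vascular endothelial-like and 11 progenitor-like. Of the 35 jam2b_mCherry cells, 13 were in cluster 1, 12 in cluster 10, and 3 each were vascular endothelial-like and progenitor-like. Independent detection within vascular endothelial-like cells would give 41.4 (etv2_Venus) and 2.90 (jam2b_mCherry) cells, and within progenitor-like cells 10.8 and 2.84, near the numbers found. In clusters 1, 5, 6, 10 and 27 of the jam2b_mCherry library 27 cells had both genes (0.506 to 1.11%) against 20.5 for independent detection. That interval covers 20.5 cells, and 1 of 3272 thinned cells of these clusters had both. In the same clusters an etv2 UMI was found in 0.995% of cells (0.694 to 1.38%, median 4931 UMIs), and in 2.93% (1.71 to 4.64%) of cluster 10, against 0.0855% (0.00220 to 0.476%) of neural progenitor-like cells (median 4148 UMIs). Thinned, the etv2 shares were 0.258% (0.0838 to 0.601%) in clusters 1 and 5 and 0.0947% (0.00240 to 0.527%) in neural progenitor-like cells. Those intervals overlap. Thinned to 2000 UMIs, 0.303% of etv2_Venus cells and 0.0580% of jam2b_mCherry cells had both.

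Over all cells the libraries differed in blood, endothelial and mesodermal genes. Of 12438 genes with enough UMIs, 1568 were at least 2-fold higher in the jam2b_mCherry library and 2279 in the etv2_Venus library. The genes pitx1 (ENSDARG00000116608, 136 against 0.720 CPM, 191-fold, 132 to 287), tbx5a (176-fold, 110 to 302), myrf (182-fold), s100a11 (166-fold), pcolcea (69.5-fold) and adamts15a (69.7-fold) were among the highest in the jam2b_mCherry library. Over the clusters, s100a11 was highest in epidermis-like cluster 23 (1508 CPM) and pitx1 in cluster 5 (627 CPM). The growth hormone gene gh1 (ENSDARG00000038185) was 71.3-fold higher there (60.6 to 84.4), at 271 against 3.81 CPM. The genes atp1a1a.2, COLEC10, prlhr2a, tectb and olfcs2 completed this group, on 1 to 4 UMIs each in the etv2_Venus library. In the etv2_Venus library the globin genes hbbe3 (ENSDARG00000038147, 6204-fold), hbae3 (2913-fold), hbbe1.2, hbbe1.3, hbbe1.1, hbbe2, hbae5 (at least 188-fold) and hbae1.1 (at least 3310-fold) led, with the erythroid transporter gene slc4a1a (1153-fold). The neutrophil gene lyz (ENSDARG00000057789) was 304-fold higher (285 to 325), and f8 and cfh were at least 225-fold and at least 81.1-fold higher.

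Fixed gene lists over all cells followed the cell classes. Medians take every member with at least 20 UMIs, and numbers of genes past the 2-fold limit take members past the higher minimum for calls. Mature endothelial genes had a median log2 ratio (jam2b_mCherry over etv2_Venus) of -6.13, with 9 of 9 higher in the etv2_Venus library, among them cdh5 (1338 against 18.1 CPM), cldn5b and plvapb. Vascular progenitor genes had a median of -4.82 (0 higher in the jam2b_mCherry library, 8 in the etv2_Venus library and 0 neither, of 8, with lmo2, tmem88a, sox7), venous genes -4.56 (0, 7 and 3 of 10, with stab2, dab2), VEGF receptor genes -4.32 (0, 13 and 2 of 15, with aplnrb, esm1), arterial genes -2.96 (1, 10 and 3 of 14, with aqp1a.1, efnb2a, and notch3 in the opposite direction) and lymphatic genes -2.53 (2, 7 and 2 of 11, with tspan18b, flt4). Glycolysis genes had a median of -1.56 (0, 14 and 4 of 18), with gapdhs at 601 against 89.6 CPM and eno3 at 153 against 37.7 CPM. These 7 medians were below all 10000 random lists (percentile 0).

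Mesothelial and lateral plate genes had a median of 3.17 (10 higher in the jam2b_mCherry library, 1 in the etv2_Venus library and 1 neither, of 12), with aldh1a2 at 244 against 12.3 CPM and hand2 at 120 against 6.41 CPM, and podxl in the opposite direction. Epithelial-mesenchymal transition genes had a median of 1.89 (7, 0 and 5 of 12, with cdh2, twist1a, prrx1a), Hedgehog genes 1.77 (7, 0 and 2 of 9, with boc, hhip), retinoic acid genes 1.53 (6, 1 and 4 of 11, with rdh10a, crabp2b) and Wnt genes 1.53 (8, 0 and 1 of 9, with sfrp5, lef1, axin2). Hypoxia and angiogenic ligand genes reached 1.15 (4, 4 and 2 of 10, with apela, and apln in the opposite direction), proliferation genes 1.01 (11, 0 and 10 of 21, with pcna, mki67, rrm2), BMP genes 0.96 (9, 3 and 7 of 19, with id1 and id3 past no limit) and extracellular matrix genes 0.91 (11, 6 and 4 of 21, with col1a2, col5a1). The hypoxia list fell at percentile 99.98 and the other 8 at 100.

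The other lists lay less far out among the random lists, at percentiles 0.920 to 25.2. Iron and heme genes had a median of -0.98 (0, 4 and 6 of 10, with hmox1a, percentile 0.920), endocardial genes -0.87 (3, 4 and 1 of 8, with fn1a and notch1b in opposite directions, percentile 2.48), lipid transport genes -0.86 (0, 3 and 1 of 4, with fabp11a, apoeb, percentile 2.86), apoptosis genes -0.74 (0, 3 and 7 of 10, with sesn1, percentile 2.73) and junction genes -0.54 (3, 7 and 3 of 13, with tjp1a, percentile 2.29). Oxidative phosphorylation genes had a median of -0.14 (0, 0 and 19 of 19, with cox7c, cox6a1, percentile 11.4), Notch genes -0.14 (5, 5 and 6 of 16, with her6 higher in the jam2b_mCherry library, percentile 19.8) and dissociation stress genes -0.05 (2, 5 and 13 of 20, with fosab, jun, btg2, percentile 25.2).

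**Figure D3:**
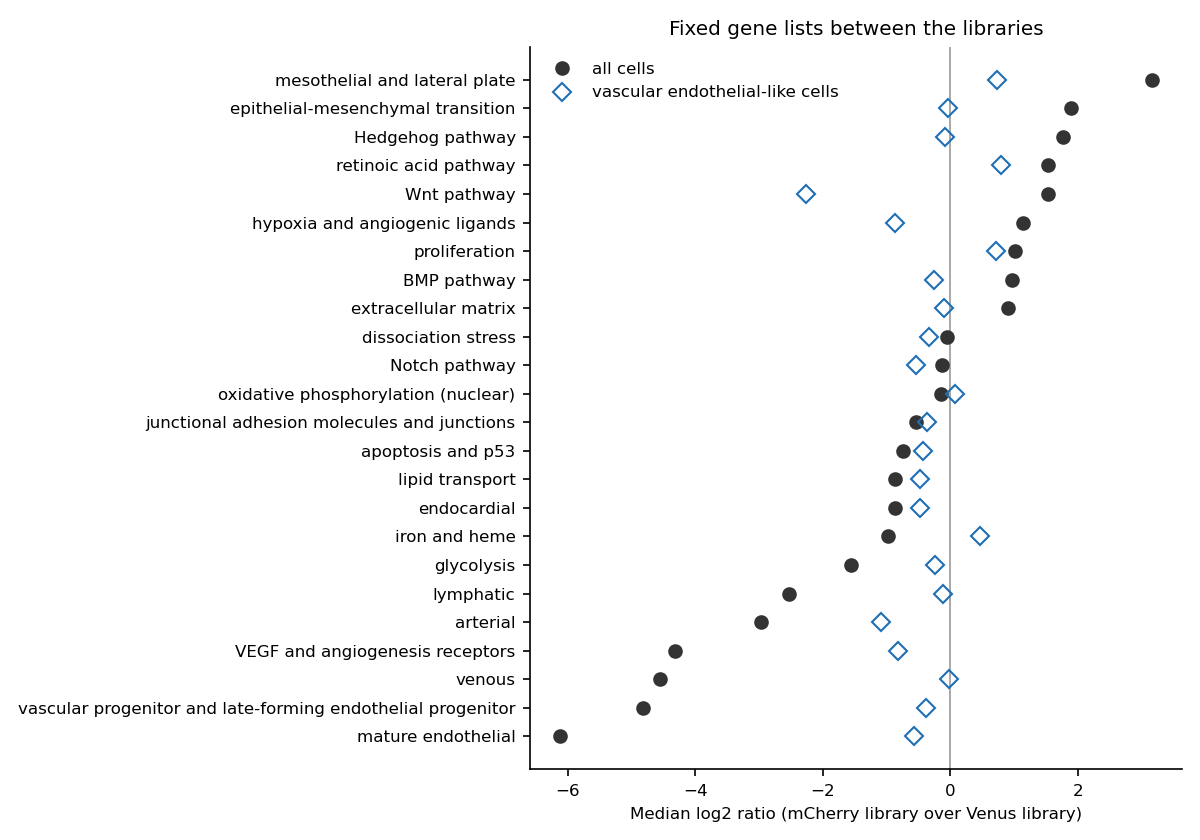
Median log2 CPM ratio of the jam2b_mCherry over the etv2_Venus library for each fixed gene list, over all cells (filled circles) and within vascular endothelial-like cells (open diamonds). Mature endothelial genes lie at -6.13 over all cells and at -0.56 within vascular endothelial-like cells, and arterial genes at -2.96 and -1.09 (-0.11 within vascular endothelial-like cells at a matched cluster mix).

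The next comparison asked how the vascular endothelial-like cells of both sorts differed. Arterial genes were lower in the 81 jam2b_mCherry cells than in the 5133 etv2_Venus cells, but not when the cluster mix was matched. Their median log2 ratio was -1.09, below all random lists, and of 14 members 8 were lower and 0 higher. Levels were 1799 against 4889 CPM for aqp1a.1, 574 against 1598 CPM for cldn5b, 214 against 434 CPM for efnb2a and 156 against 342 CPM for flt1. Venous genes stood level, with a median of -0.01 and 10 of 10 past no limit, such as stab2 at 1141 against 1185 CPM and dab2 at 1058 against 1038 CPM. Vascular cells of the jam2b_mCherry library lay mostly in cluster 0 (46 of 81), while cluster 0 held 1377 and cluster 3 held 1033 of the 5133 etv2_Venus cells. With etv2_Venus cells drawn to the same cluster mix, a comparison chosen after seeing the data, the arterial median was -0.11 (-0.17 to -0.01 over 20 further draws), with 0 genes past the limit, and the venous median was -0.32. The clusters were drawn from the same expression values, and the arterial genes flt1, dll4 and aqp1a.1 are among the leading genes of cluster 3. The matched values place the arterial difference in the spread over clusters and are no separate test of it.

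Of 9542 genes, 190 were at least 2-fold higher in the vascular endothelial-like cells of the jam2b_mCherry library and 379 in those of the etv2_Venus library, a split of 33.4% towards jam2b_mCherry. In simulated sums of the same depth, 128 of 9201 unchanged genes passed the same limit. Those sums held Poisson noise only, without variation between cells, so the number of false calls in the real sums may be larger. With CPM scaled by the median ratio over genes, the numbers were 289 and 254, a split of 53.2%. At the matched cluster mix (2349 etv2_Venus cells) they were 81 and 208 (70 to 84 and 198 to 219 over 20 further draws), of which 66 and 167 were shared with the calls over all vascular cells. Among genes past the minimum of 100 UMIs, the highest in the jam2b_mCherry cells were tonsl (ENSDARG00000071294, 5.92-fold, 2.86 to 11.1), col12a1a (5.41-fold), fgfr3 (4.98-fold), fabp7a (4.62-fold), kif26ba, rhag, col11a1a, ddb2, col16a1, col1a1a (3.78-fold), nat8l and rbp5, on 7 to 20 UMIs each. Below that minimum, gh1 stood at 79.4 against 0.795 CPM (30 and 16 UMIs). All 12 genes from tonsl to rbp5 were highest in clusters outside the vascular ones, such as fgfr3 in cluster 5 (1512 CPM) and fabp7a in neural progenitor-like cluster 9 (3026 CPM), so RNA of such cells is not excluded. For col1a1a the log2 ratio was -0.18 at 1000 genes per cell with the cells clustered again, and 1.72 with the class kept. In the etv2_Venus cells lyz (at least 9.88-fold), mia (at least 7.80-fold), hbegfb, adra1aa (at least 4.47-fold), kng1, paqr3b, RASSF10, slco1d1, rusc2 and the globin genes hbbe1.3, hbae3 and hbbe3 were highest, with 0 UMIs in the jam2b_mCherry cells. Of these, lyz and the globin genes belong to blood classes present in the etv2_Venus library. In neural progenitor-like cells, 10.5% of the genes called towards the etv2_Venus library moved 2-fold the same way, against 5.53% of all genes measured there, and 3.33% against 3.26% in the other direction.

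Other lists within vascular endothelial-like cells moved in both directions. Proliferation genes had a median of 0.72 (4 higher in the jam2b_mCherry library, 0 lower and 17 neither, of 21, percentile 100), with pcna at 476 against 264 CPM, mki67 at 333 against 196 CPM and plk1 at 220 against 101 CPM. VEGF receptor genes had a median of -0.82 (0, 4 and 11 of 15, percentile 0), with kdrl at 394 against 695 CPM, and mature endothelial genes -0.56 (0, 1 and 8 of 9, with cdh5, plvapb, percentile 0.0400). Wnt genes had a median of -2.26 (0, 3 and 2 of 5, with nkd1, lef1 and axin2, on 17, 2 and 1 UMIs in the jam2b_mCherry cells, percentile 0.0400). Notch genes had a median of -0.54 (0, 4 and 11 of 15, with dll4, notch1b, percentile 0.660) and hypoxia genes -0.87 (0, 2 and 4 of 6, with apln at 84.7 against 318 CPM, percentile 1.46). Retinoic acid genes had a median of 0.79 (0, 1 and 3 of 4, with dhrs3a lower, percentile 99.5), mesothelial genes 0.74 (0, 1 and 2 of 3, with bnc2 lower, percentile 99.3) and iron genes 0.47 (0, 0 and 6 of 6, with fth1a, percentile 99.8). Over 20 further draws at the matched cluster mix, medians ranged from 0.29 to 0.47 for proliferation, -0.42 to -0.34 for VEGF receptor, -0.57 to -0.43 for hypoxia and -0.59 to -0.52 for mature endothelial genes, with 0 genes past the limit. They ranged from -1.90 to -0.79 for Wnt genes (2 past the limit), -0.02 to 0.24 for Notch genes (0 to 2), -0.44 to 0.24 for mesothelial genes (1), 0.25 to 0.47 for iron genes (0 to 1) and 0.52 to 0.81 for retinoic acid genes (0 to 1).

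The remaining lists within vascular endothelial-like cells had medians between percentiles 4.04 and 81.1. They were -0.48 for lipid transport (0, 1 and 3 of 4, with fabp11a at 249 against 1319 CPM), -0.47 for endocardial (0, 1 and 4 of 5, with klf2a), -0.42 for apoptosis (0, 1 and 8 of 9, with ccng1), -0.39 for vascular progenitor (0, 1 and 7 of 8, with tmem88a, and etv2 lower), -0.37 for junction (0, 1 and 9 of 10, with tjp1a, jam3b) and -0.34 for dissociation stress genes (0, 1 and 16 of 17, with jun, btg2). They were -0.26 for BMP (0, 0 and 13 of 13, with id1, smad5), -0.23 for glycolysis (0, 1 and 14 of 15, with gapdhs, aldoaa), -0.11 for lymphatic (0, 0 and 9 of 9, with mrc1a, stab2) and -0.10 for extracellular matrix genes (2, 5 and 9 of 16, with col4a1 and col4a2 lower). For Hedgehog genes the median was -0.08 (0, 0 and 7 of 7, with smo), for epithelial-mesenchymal transition genes -0.04 (0, 0 and 8 of 8, with zeb1b) and for oxidative phosphorylation genes 0.07 (1, 0 and 18 of 19, with cox7c). Over 20 further draws at the matched cluster mix, medians ranged from -0.53 to -0.41 for endocardial, 0.28 to 0.56 for Hedgehog and -0.05 to 0.49 for lipid transport genes. They ranged from -0.37 to -0.14 for apoptosis, -0.38 to -0.30 for vascular progenitor, -0.26 to -0.21 for junction and -0.33 to -0.29 for lymphatic genes. Ranges were -0.17 to -0.10 for dissociation stress, -0.12 to 0.005 for BMP, -0.05 to 0.06 for glycolysis and -0.40 to -0.18 for extracellular matrix genes. For epithelial-mesenchymal transition genes the range was 0.07 to 0.36, and for oxidative phosphorylation genes 0.06 to 0.12.

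The comparisons within progenitor-like cells and within cluster 0 were added after seeing the data. Progenitor-like cells of both sorts shared high etv2, tal1 and lmo2 and differed in other genes. The 19 jam2b_mCherry cells had more cfd (ENSDARG00000039579, 509 against 71.8 CPM, 7.09-fold, 5.33 to 9.40), nanos1 (ENSDARG00000109337, 761 against 109 CPM, 7.003-fold, 5.56 to 8.80), ndnf (ENSDARG00000062936, 1013 against 153 CPM, 6.64-fold, 5.45 to 8.07) and fgfr2 (ENSDARG00000058115, 446 against 98.0 CPM, 4.55-fold, 3.43 to 5.998) than the 226 etv2_Venus cells. Both ndnf and nanos1 had a UMI in 19 of 19 jam2b_mCherry cells, against 26.1% and 20.8% of the etv2_Venus cells, at medians of 9570 and 7330 UMIs. In neural progenitor-like cells ndnf was found in 11.8% and 19.1% of cells and nanos1 in 4.19% and 3.36% (jam2b_mCherry and etv2_Venus). The genes gh1 (4.34-fold), tmem88b (4.04-fold), myl6, her6, fosab, aldh1a2, tpx2 and cxcl12a (3.27-fold) were also higher in the jam2b_mCherry cells. For cxcl12a, however, the ratio was 1.64 (0.796 to 3.05) without the 6% of highest doublet scores, and 1.84 (0.859 to 3.50) in the 9 cells with the lowest scores. In the etv2_Venus cells matn4 (at least 17.0-fold), cldn5b (at least 6.09-fold), sox13 (at least 5.15-fold), sema3ab, tlx2, slc29a1b, rspo3, pknox2, gata1a and fam43a were higher, with 0 UMIs in the jam2b_mCherry cells. There aqp1a.1 was 28.9-fold (5.14 to 1144) and tnc 22.0-fold (7.51 to 107) higher. In neural progenitor-like cells aqp1a.1 (84.2 against 1.33 CPM, 63.4-fold), matn4 (6.80-fold) and cldn5b (4.07-fold) were also higher in the etv2_Venus library. The other genes named towards etv2_Venus were not among the 12 highest there. Towards jam2b_mCherry, gh1 (20.6 CPM against 0 UMIs) and aldh1a2 (68.1 against 27.4 CPM, 2.49-fold) were also higher in neural progenitor-like cells. Over clusters held by both libraries, aqp1a.1 was called towards etv2_Venus in 15 of 15, and gh1 and aldh1a2 towards jam2b_mCherry in 11 and 6. For aqp1a.1, matn4, cldn5b, gh1 and aldh1a2 the direction is thus not particular to progenitor-like cells. In all, 63 of 2075 genes were higher in the jam2b_mCherry and 202 in the etv2_Venus cells. The doublet scores of the 19 cells were high, with their median at percentile 94.1 of their library, and with the 6% of highest scores removed 11 of the 19 were left. In these 11 cells cfd (8.64-fold), nanos1 (7.40-fold), ndnf (7.41-fold) and fgfr2 (5.40-fold) were still called higher.

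**Figure D4:**
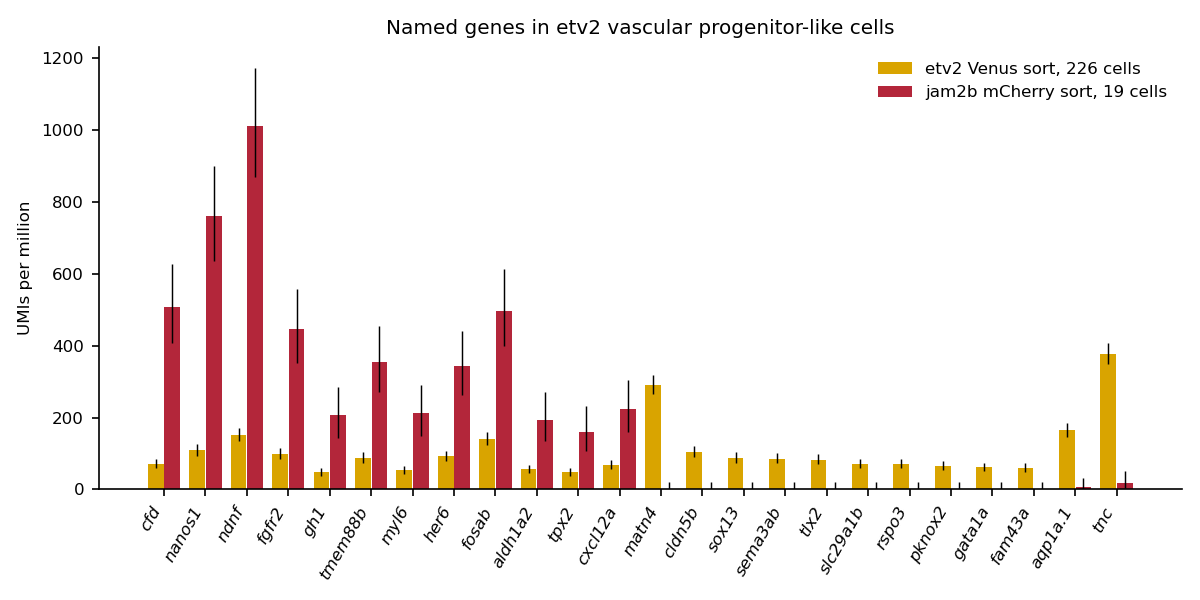
CPM of the named genes in progenitor-like cells of the etv2_Venus library (226 cells) and the jam2b_mCherry library (19 cells), with exact Poisson 95% intervals that cover counting error only. The genes from cfd to cxcl12a are higher in the jam2b_mCherry cells and those from matn4 to tnc in the etv2_Venus cells.

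Within cluster 0 the same pair of genes was higher in the 46 jam2b_mCherry cells than in the 1377 etv2_Venus cells. The ratio was 6.54-fold for ndnf (4.46 to 9.39, 187 against 28.6 CPM) and 4.93-fold for nanos1 (2.70 to 8.47, 78.8 against 16.0 CPM). The genes slc16a10 (4.97-fold, 374 against 75.3 CPM), ccl38.1 (5.55-fold), ppp1r9alb, spry4, vezf1b, ctbp2a, rfc5, myo6a, nap1l4a and col1a1a (2.97-fold, on 11 UMIs in 5 of the 46 cells, 5 of them in 1 cell) were also higher. A ndnf UMI was found in 21.7% of the jam2b_mCherry and 5.81% of the etv2_Venus cells of cluster 0, at medians of 4170 and 3481 UMIs. In the etv2_Venus cells of cluster 0, cxcl12b, ctgfa, cyr61l2, tp53inp1, rai14, srsf2b, tbc1d10aa, fam208ab and cmtm8b were at least 1.99-fold to at least 2.42-fold higher, with lyz, hbbe1.3 and hbae3 beside them. Of these, cyr61l2 was also 4.30-fold higher in neural progenitor-like cells of the etv2_Venus library.

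The last comparison set vascular endothelial-like cells with a jam2b UMI against those without, in each library on its own. It held 60 cells with and 5073 without in the etv2_Venus library, and 5 with and 76 without in the jam2b_mCherry library. In both libraries, col1a2 (ENSDARG00000020007) was higher in cells with jam2b (2.17-fold, 1.79 to 2.61, and 2.66-fold, 1.14 to 5.51), and CABZ01079276.1 was lower (ratios 0.495, 0.358 to 0.668, and 0.130, 0.00330 to 0.740). No other gene passed in both, and the pair was lost under 4 of 5 other settings. No gene passed in both when cells were thinned to 2000 UMIs or doublets were kept, and other genes did with 2 jam2b UMIs required (7, such as lgmn, mki67 and ndnf) or with progenitor-like, endocardium-like and cluster 18 cells added (4, such as cfd, fgfr2 and tal1).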

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

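All tests in this part were chosen after the result was seen. Signals in data that the comparisons did not use were looked for among the added features and the barcodes left out. The added row ets1a held 4056 UMIs in the etv2_Venus library and 692 UMIs in the jam2b_mCherry library, above the limit that a count of 0 allows. Almost any detected feature passes that limit, so passing it shows only that a signal is present. In vascular endothelial-like cells it stood at 166 and 161 CPM, while the annotated ets1 feature held 163 and 23 UMIs over all cells. The sequence behind the added row is not given in the sources used here. Of the etv2_Venus barcodes removed by the filters, 42.6% had an etv2 UMI, also above that limit. The share was 62.2% of the 487 removed for their doublet score alone (median 5929 UMIs) and 25.7% (22.1 to 29.5%) of the 564 under 500 genes or over the mitochondrial limit (median 650 UMIs). As background, it was 3.69% of neural progenitor-like cells of that library (median 4157 UMIs) and 0.337% of the removed low-gene or mitochondrial barcodes of the jam2b_mCherry library. Whether the low-gene barcodes held cells or free RNA was not tested.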

How the results depend on the processing

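The alternatives with a matched cluster mix, clusters of each library alone named against both, the class kept at 1000 genes per cell, wider vascular cell sets, blood-like cells left out or the 6% of highest doublet scores removed in both libraries, and all those for progenitor-like cells, were chosen after seeing the data. No paired analysis was possible because each group has 1 library. The vascular endothelial-like share of the etv2_Venus library (68.1%) was 69.5% with every barcode, 66.8% with doublets kept, 71.9% at resolution 0.5 and 43.1% with each library clustered on its own. Named against cells of both libraries, those clusters gave 67.0%, so most of the fall came from comparing markers within a mostly vascular library. In the jam2b_mCherry library (1.07%) it was 1.33% on its own, and 0% named against both, where those cells took the progenitor-like name. With a minimum of 20 UMIs, which admits more genes, calls over all cells were 3012 and 3718 (jam2b_mCherry and etv2_Venus) and within progenitor-like cells 254 and 358. Within vascular endothelial-like cells, scaling by the median ratio gave 289 towards jam2b_mCherry, a matched cluster mix 81 and 208, and adding progenitor-like, endocardium-like and cluster 18 cells 288 and 672. Lists with a median of at least 1 in size there (2) numbered 1 with scaling, 1 with the matched mix (arterial genes fell to -0.11; 0 to 1 over further draws) and 5 with the added cells. Progenitor-like calls (63 and 202) were 110 and 391 with 3000 variable genes and etv2 and jam2b left out of them (446 and 18 cells, etv2_Venus and jam2b_mCherry). Without the 6% of highest doublet scores they were 163 towards jam2b_mCherry with the class drawn again (501 and 9 cells), and 74 and 173 with it kept (226 and 11 cells). Cells with both genes fell to 0.303% and 0.0580% when thinned, and were 0.0796% and 0.119% with 2 UMIs of each required (etv2_Venus and jam2b_mCherry). Genes shared between cells with and without jam2b (2) were 0 when thinned, 0 with doublets kept, 7 others with 2 jam2b UMIs required and 4 others with the added cells, so col1a2 and CABZ01079276.1 were kept only at a minimum of 20 UMIs. The log2 ratio of col1a1a in vascular endothelial-like cells was -0.18 at 1000 genes per cell with the cells clustered again (main 1.91) and 1.72 with the class kept, so leaving out shallow cells did not by itself reverse it, and that of cxcl12a in progenitor-like cells -0.35 without the 6% of highest doublet scores and with the class drawn again (main 1.69), but 0.70 with it kept. Other causes were not tested. Single named genes stayed within their interval in 454 of 504 values and list medians within their limit in 323 of 336. These limits differ in width. A gene with 0 UMIs in the jam2b_mCherry cells had almost no lower limit, and limits of list medians span the members. Intervals of cell shares are narrow at these numbers of cells. The numbers of values within limits thus cannot rank the kinds of result by stability. Shares of classes other than vascular endothelial-like stayed within their interval in 160 of 258 values and moved out of it in 98. The main results stayed within the limit set for each in 65 of 95 values and moved in 30. Cluster 0 values were not recomputed across clusterings, whose numbers differ.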

Other observations

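All tests in this part were chosen after the result was seen. Cluster 18 was made of 283 etv2_Venus cells and 0 jam2b_mCherry cells. Its leading genes included the water channel genes aqp8a.1 and aqp1a.1, apoc1, dnase1l4.1, hoxc13b and fabp11a, beside etv2 and eGFP. Cluster 26 (118 etv2_Venus and 6 jam2b_mCherry cells) mixed cells of different kinds. Of the etv2_Venus cells 83 had a myb UMI, while 10 or more UMIs of the crystallin genes cryba1b, crybb1 and cryba4 were found in 5 jam2b_mCherry cells and 1 etv2_Venus cell, none with myb.

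UMIs of gh1 were found in many cell types of the jam2b_mCherry library and were scarcer in most of the same types in the other library, where progenitor-like cells had 47.5 CPM and 13 cells of cluster 10 had 352 CPM. Fin bud mesenchyme-like cells of cluster 22 had 127 CPM against 0.861 CPM, vascular endothelial-like cells 79.4 against 0.795 CPM, and neural progenitor-like cells 20.6 CPM against 0 UMIs. RNA of pituitary cells is argued against by pou1f1, prl, pomca and cga, whose UMIs came to 0.0966% of those of gh1 (11 against 11386). Free RNA as the source of all gh1 UMIs is argued against by the range outside clusters 1, 5, 6, 10 and 27. There, otic and lateral line-like cells of the jam2b_mCherry library stood 42.6-fold above pigment-like cells. This range compares only a high class with a low class. It cannot exclude free RNA in classes with low levels, such as neural progenitor-like, neuron-like and pigment-like cells, where free RNA stays open. Transcripts of the sorted reporter counted on the gh1 feature stay open as a candidate explanation, since no reporter sequence was examined, and the 11 of 15 shared clusters in which gh1 was called towards jam2b_mCherry only restate the pattern.

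The gain of cfd, nanos1, ndnf, fgfr2 and 7 further named genes in progenitor-like cells of the jam2b_mCherry library was weighed next. Free RNA is argued against by a median gain in neural progenitor-like cells of -4.48% of the gain in progenitor-like cells (highest 29.4%). Doublets with cells of clusters 1, 5, 6, 10 and 27 are argued against as the whole source by those clusters' abundant genes. These reached at most 15.4% of the share needed. This highest value was for cluster 10, whose genes gave a share of 14.4% against 93.4% needed. Doublets with its cells as part of the gain are thus not excluded. Shares for the other clusters were 2.05 to 2.79%. The share needed was over 100% for clusters 6 (174%) and 27 (141%), which no doublet can reach. The gain was not confined to the cells with the highest doublet scores. In the 9 of the 19 cells with the lowest scores the median ratio was 5.01, with 10 of 11 genes at 2-fold or more. These 9 were ranked only among the 19, whose median score lay at percentile 94.1 of the library. Their own scores may thus still be high, and this split cannot exclude doublets. In the etv2_Venus library, 17 of 226 progenitor-like cells had a gh1 UMI. They were set against those without by ratio and interval alone, with no minimum of UMIs. In them 11 of 11 genes were higher by this rule (cfd 19.4-fold, 13.2 to 28.9, and ndnf 8.89-fold, 6.90 to 11.4). In 1000 random splits of the same cells into the same sizes, a median of 1 and at most 9 of the 11 genes reached 2-fold. The 11 genes are thus not separate checks, and the intervals leave out variation between cells. Of these, myl6, aldh1a2 and tpx2 held under the 100 UMIs required of other calls within a class. By the same rule 10 of 12 genes of the opposite direction were lower. On few UMIs, jam2b (7.73-fold, 2.21 to 25.4, 6 against 8 UMIs), the cluster 5 gene pcolcea (6.44-fold, 3.14 to 12.8, 15 against 24 UMIs) and hand2 (4 against 0 UMIs) were also higher. Ratios were below 1 for eGFP (0.397, 0.297 to 0.521), etv2 (0.632, 0.527 to 0.752) and lmo2 (0.616, 0.549 to 0.690). Levels of tal1 were similar (0.953, 0.827 to 1.09), and npas4l (1.38, 1.08 to 1.76) was above 1. Median doublet score percentiles were 78.0 with and 44.6 without gh1. By the abundant genes of cluster 10, the cells with gh1 held 11.2% of its RNA beyond those without. Double-positive cells were added by hand to both sorts, per the labels, so mCherry-positive cells are present in each library. Whether the progenitor-like cells with gh1 are among them was not tested. A subset of progenitor-like cells tied to the mCherry sort may exist in both libraries, as a hypothesis. Doublets with cluster 10 cells as part of the gain, or with a cell type not examined, stay open. Either would also lower etv2 and eGFP.

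The kdrl UMIs of clusters 1 and 5 in the jam2b_mCherry library were set against those of other endothelial genes. Endothelial RNA, free or from doublets, would bring cdh5, pecam1, tie1, tek, esama, cldn5b, plvapb, ptprb and vwf in the ratio seen in vascular endothelial-like cells, and their 116 UMIs were 1.02% of the 11363 UMIs called for, with ptprb the highest of the more abundant genes at 16.9%. A level shared by all cells of the library is argued against by 18.7% of thinned cells with a kdrl UMI, above the 0.654% upper limit of fin bud mesenchyme-like cells. Expression of kdrl in jam2b-positive cells of clusters 1 and 5 may account for it as a hypothesis, while reads of another gene counted as kdrl were not examined.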
